A study of Homo sapiens with 4 samples.

How the data were processed

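Total RNA of A549 cells was taken 24 hours after transfection with miR-509-3p mimic or negative control mimic and hybridised as biotin-labelled cRNA, per the labels' protocols. The groups came from the labels, with 2 arrays in each, and no column of sample values went unused.

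The authors deposited a table of probe intensity on a linear scale, not normalized between arrays, which the submitters' processing notes credit to GenomeStudio 2009.2. Beside each intensity the authors deposited a detection p-value, whose values moved in steps of 1 part in 770. The authors also deposited processed values on a log2 scale for 19069 probes, all of which, and no others, had a detection p under 0.05 on at least 2 arrays. How these were made is not given in the sources used here. The sorted values of each array lay within 0.0008 of the log2 of the mean sorted signals, as quantile normalization of the signals gives, and the median was 9.42 on each array. Each array's values, centred by probe, correlated at 0.979 or more with that array's own centred log2 signals, so their scale and direction followed from the signals.

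Signals were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected background by normexp with the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Probes detected at p under 0.01 on at least 2 of the 4 arrays were kept, which left 16561 of 47320. Probes were named through the platform annotation, which gave 1 gene name for 30113 probes, several for 8 and none for 17199. Names were updated through the gene table of a human reference assembly (GRCh38.p14), in which 30092 named probes were matched, and 21 kept the annotation's name. A gene was represented by its kept probe with the highest mean over the 4 arrays, which gave 10239 genes, of which 2638 had 2 or more kept probes. A further 3133 kept probes had no single gene name and entered no gene test. No coordinates are given because the array files name no genome build.

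Groups were compared with lmFit and eBayes without covariates, and p-values were adjusted by Benjamini-Hochberg over genes, with calls at an adjusted p under 0.05. The fits had 2 residual and 2.48 prior degrees of freedom. A gene undetected on every array of 1 group has only a bound there. Its fold was set as the other group's mean against the mean, over the arrays of the dim group, of the higher of the lowest detected signal and the probe's own value. The 26 gene lists were written before the data were examined, and 21 had 5 or more measured genes and were tested with camera at its preset correlation of 0.01 and at an estimated correlation, and with fry. Their p-values were adjusted by Benjamini-Hochberg over lists. The result of 1 tested list, with its members, is not reported here.

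Genes were named by a rule fixed before the data were examined, namely the 3 study targets, the 12 genes with the largest fold in each direction among those called without overlap, and up to 4 called members of each list with the largest fold. A planned test of genes with seed matches in the 3 prime UTR, and the genes it would have named, were left out because no UTR sequence was used here. The slide and scan date are not given in the sources used here, so no batch was tested. The alternatives tried were other background and scaling choices, the authors' processed values, other probe filters, another variance model, a replicate block, averaged probes and leaving out each array in turn.

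The fit was tested on simulated data for 10239 genes. Each gene's variance was its value on these arrays after limma had shrunk it towards that of all genes. It recovered 22 of 64 genes changed by 0.5 on the log2 scale, 61 of 64 changed by 1 and 60 of 60 changed by 2, and called 4 of 10014 unchanged genes. Of 21 simulated lists, camera called 1, the one shifted by 0.3. The simulated genes were drawn independently and few were changed. False calls under correlation between genes, with as many changes as here, or with variances not shrunk, were thus not tested. Figures were drawn with matplotlib 3.10.9.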

Results

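The series measured mRNA levels in A549 cells, a line derived from a human lung adenocarcinoma, 24 hours after transfection with a synthetic mimic of the microRNA miR-509-3p or with a negative control mimic. Each group held 2 Illumina bead arrays, on which 47320 probes were read. The median probe signal was 202 and 205 on the control arrays and 207 on both mimic arrays, and 33.7%, 34.7%, 34.5% and 34.5% of the probes were detected on control 1, control 2, mimic 1 and mimic 2. Across genes, which are not independent replicates, the normalized log2 values correlated at r = 0.993 between the control arrays and 0.995 between the mimic arrays. The correlations across groups lay between 0.970 and 0.972. The median absolute log2 difference between arrays was 0.12 and 0.10 within groups and 0.26 to 0.28 across groups. The number of arrays limits the precision of each value.

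The comparison of the mimic with the control asked which transcripts miR-509-3p silences. CDK2, which encodes a kinase needed for S phase entry, fell from a normalized log2 signal of 12.02 ± 0.06 to 9.70 ± 0.05 (SD, n = 2 each), which is 4.99-fold lower. PIK3C2A, a class II phosphoinositide 3-kinase, fell from 10.89 ± 0.03 to 9.48 ± 0.02, which is 2.65-fold lower. RAC1, a small GTPase, fell from 13.37 ± 0.04 to 12.49 ± 0.02, which is 1.85-fold lower. The adjusted p-values from limma with Benjamini-Hochberg adjustment were 0.00226, 0.00228 and 0.00396 over all genes tested. Adjusted over the list alone, with the same limma test and Benjamini-Hochberg, they were 9.51e-06, 2.90e-05 and 0.000166, so all 3 passed both ways. These 3 genes were listed from recall of the study's targets, which was not checked here, and the study may have chosen them on these arrays, so their fall is not independent evidence. The second kept probe of each gene had a log2 fold change of -1.02 for CDK2, -1.42 for PIK3C2A and -1.03 for RAC1. All 3 passed. The second RAC1 probe averaged only log2 6.69 over all arrays, so the size of its fall rests on levels near background.

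**Figure D1:**
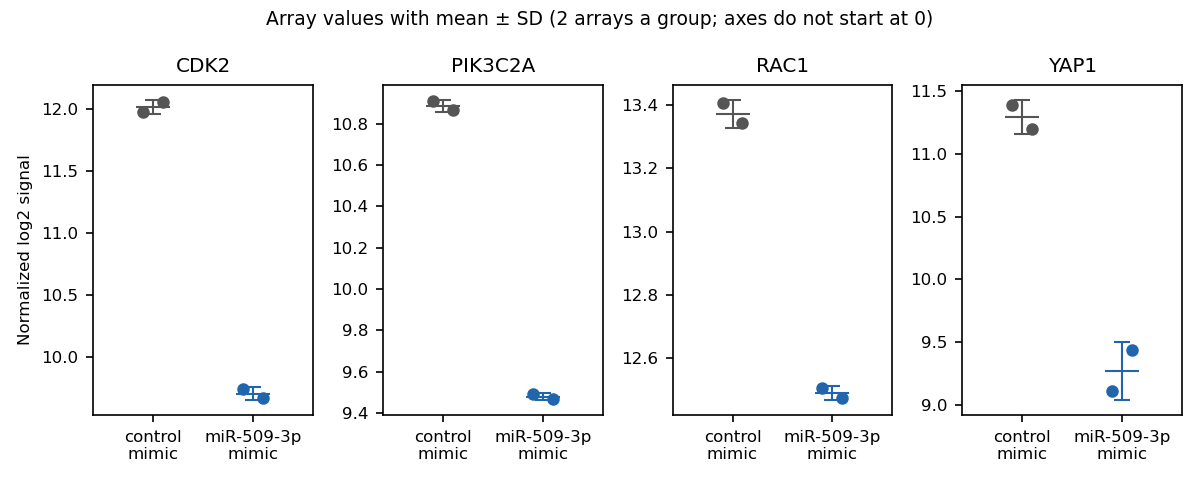
Normalized log2 signal (vertical axes, which do not start at 0) of CDK2, PIK3C2A, RAC1 and YAP1 on the 2 control mimic and 2 miR-509-3p mimic arrays; points are arrays, and bars are means ± SD. Both mimic arrays lie below both control arrays for each of the 4 genes, with means of 9.70 against 12.02 for CDK2 and 9.27 against 11.30 for YAP1.

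Among 5 genes listed, also from recall, as targets reported elsewhere, 3 were measured and all 3 fell. YAP1, the transcriptional coactivator of the Hippo pathway, fell by 2.03 ± 0.15 on the log2 scale (estimate ± SE, 4.07-fold lower). NTRK3, the receptor for neurotrophin-3, fell by 1.08 ± 0.08, and the kinase gene MAP3K8 fell by 0.66 ± 0.07. All 3 also passed when adjusted over the list alone. CFTR and XIAP had no kept probe.

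Among the 12 widest falls, ESYT2, which tethers the endoplasmic reticulum to the plasma membrane, fell by 2.80 ± 0.08 (6.98-fold lower). CMTM6, which stabilises PD-L1 at the cell surface, fell by 2.74 ± 0.11, and MMGT1, a subunit of the endoplasmic reticulum membrane complex, fell by 2.70 ± 0.07. NETO2, an auxiliary subunit of kainate receptors, fell by 2.69 ± 0.08. FAM20C, a kinase of secreted proteins, fell by 2.66 ± 0.14. Its mimic arrays averaged only log2 6.84, so this size rests partly on a level near background. DDAH1, which degrades asymmetric dimethylarginine, fell by 2.57 ± 0.10. UHMK1 fell by 2.52 ± 0.09. ABCB10, a transporter of the mitochondrial inner membrane, fell by 2.46 ± 0.07, and MCFD2, which helps carry coagulation factors out of the endoplasmic reticulum, fell by 2.45 ± 0.10. RAB5C, a GTPase of early endosomes, fell by 3.85 ± 0.11, but its probe was detected on 1 of the 2 mimic arrays. This size thus rests partly on a level near background. Its second kept probe fell by 2.66 ± 0.10, but averaged only log2 6.94 over the 4 arrays. The size of that fall also rests on levels near background. GLI2, a transcription factor of Hedgehog signalling, was not well above background on either mimic array and was at least 3.78-fold lower there. CHRAC1, a histone-fold subunit of chromatin remodelling complexes, was likewise undetected with the mimic and at least 3.93-fold lower. The 12 genes had limma adjusted p-values of 0.00226 or 0.00228 after Benjamini-Hochberg adjustment, and each was lower on 2 of 2 mimic arrays than on either control array.

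Among the 12 widest rises, NHLRC3 rose by 2.38 ± 0.07 (5.19-fold higher). DCP2, the mRNA decapping enzyme, rose by 2.03 ± 0.13 (4.09-fold higher), and DNAAF11, which assembles ciliary dynein arms, rose by 1.98 ± 0.09. ANKRD22 rose by 1.98 ± 0.08, LIAT1 by 1.90 ± 0.09 and CCDC32 by 1.89 ± 0.09. ZW10, a kinetochore protein of the spindle checkpoint, rose by 1.83 ± 0.08, and GBP2, an interferon-inducible GTPase, rose by 1.80 ± 0.14. A further 4 genes were not well above background on either control array. Of these, RSPH1, a radial spoke head protein of cilia, was at least 1.59-fold higher with the mimic, and ELFN2 was at least 3.83-fold higher. The antisense transcript DLG5-AS1 was at least 2.26-fold higher, and the zinc finger gene ZNF664 was at least 1.90-fold higher. The limma adjusted p-values of the 12 genes lay between 0.00226 and 0.00338 after Benjamini-Hochberg adjustment.

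**Figure D2:**
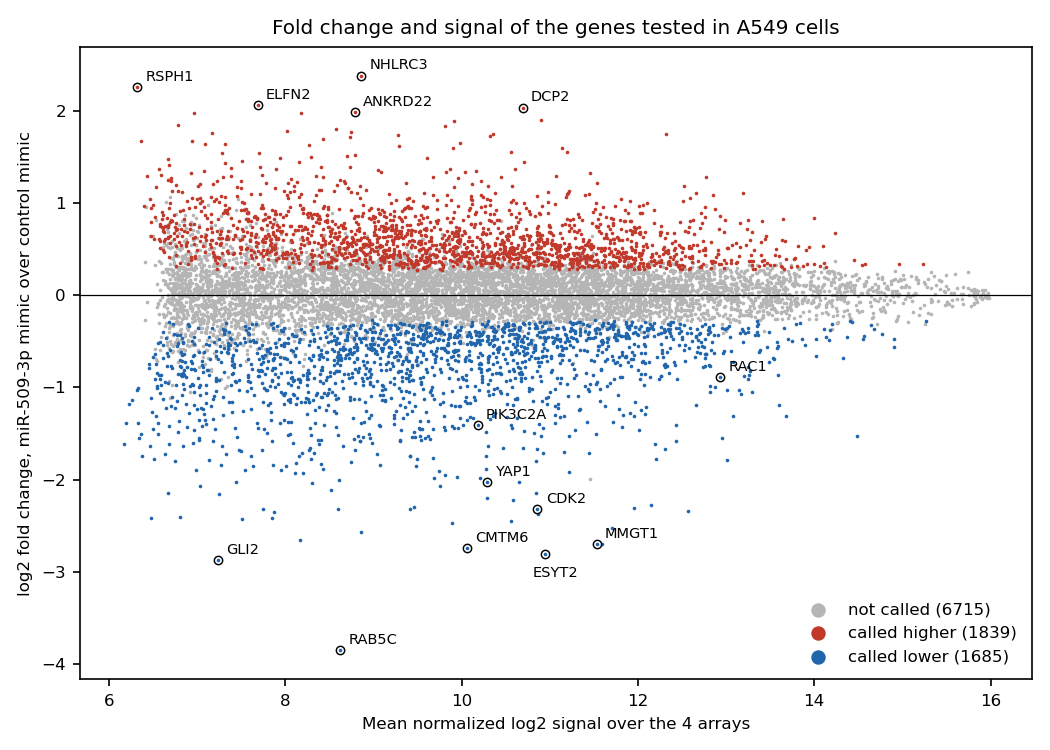
The log2 fold change of miR-509-3p mimic over control mimic (vertical axis) against the mean normalized log2 signal over the 4 arrays (horizontal axis) for the 10239 genes tested; red points are the 1839 genes called higher, blue points the 1685 called lower and grey points the genes not called. The named genes are circled, and RAB5C, detected on 1 of the 2 mimic arrays, is at -3.85.

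In all, 1839 of 10239 genes were higher and 1685 were lower with the mimic at an adjusted p under 0.05 (limma, Benjamini-Hochberg), or 34.4% of the genes. All 3524 called genes had no overlap between groups, as did 72.9% of all genes, where chance gives 33.3%. Over 1.5-fold without overlap, 917 genes were higher and 1057 lower. Over 2-fold, a threshold added after the data were seen, 180 were higher and 419 lower. Without background correction, 62 were higher and 213 lower over 2-fold. The labels do not say that the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The counts of genes called higher and lower were 1137 and 1080 without control 1, 1050 and 1046 without control 2, 270 and 556 without mimic 1 and 351 and 615 without mimic 2; without a filter on dim probes, they were 768 and 961, with median scaling 1312 and 1662 and with the replicate block 1306 and 1328, while without background correction 459 and 699 genes passed 1.5-fold.

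Mitotic genes fell as a group. The limma camera test gave an adjusted p = 0.0274 (Benjamini-Hochberg over 21 lists), and adjusted p = 0.574 with an estimated correlation. Of 44 measured genes of mitosis and G2/M, 15 fell, 2 rose and 27 did not pass, with the same counts adjusted over the list alone and a mean log2 fold change of -0.20. FOXM1, a transcription factor of mitotic genes, fell by 1.35 ± 0.09, HMMR, a spindle protein, fell by 1.23 ± 0.09, the phosphatase gene CDC25C by 0.63 ± 0.09 and the kinetochore gene NUF2 by 0.62 ± 0.12.

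Targets of YAP and TAZ also fell as a group, with a mean log2 fold change of -0.43. The limma camera test gave an adjusted p = 0.0487 (Benjamini-Hochberg), and adjusted p = 0.574 with an estimated correlation. The limma fry test, which does not compare a list with the other genes, gave adjusted p = 0.00588 for mitosis and 0.00685 for these targets (Benjamini-Hochberg). Of 20 measured, 10 fell, 3 rose and 7 did not pass; adjusted over the list alone, 12 were lower and 4 higher. The receptor kinase gene AXL fell by 2.14 ± 0.08, CRIM1 by 1.80 ± 0.12, the stress gene GADD45B by 1.30 ± 0.09 and PTPN14, a phosphatase that restrains YAP, by 1.01 ± 0.14. The second kept probe of PTPN14, at a lower signal, had a log2 fold change of -0.00017 ± 0.27 and did not pass. CCN2 fell by 0.77 ± 0.10 while CCN1, its close relative, rose by 0.38 ± 0.08; these 2 were chosen after their values were seen. Neither list passed with an estimated correlation. The estimate was -0.020 for mitosis and -0.023 for YAP and TAZ targets, below the preset 0.01. With an estimate, camera tests on the 2 residual degrees of freedom of the fit. It therefore had little power here, and its outcome cannot decide whether correlation accounts for these calls. Without control 1, the camera adjusted p was 0.0748 for both lists (limma, Benjamini-Hochberg). For the YAP and TAZ targets it was 0.0570 without control 2 and 0.0782 without mimic 2 by the same limma test and Benjamini-Hochberg adjustment. Averaging the probes of a gene gave a limma camera adjusted p of 0.0558 for mitosis and 0.0653 for YAP and TAZ targets, and no filter on dim probes gave 0.0598 for the latter (Benjamini-Hochberg).

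**Figure D3:**
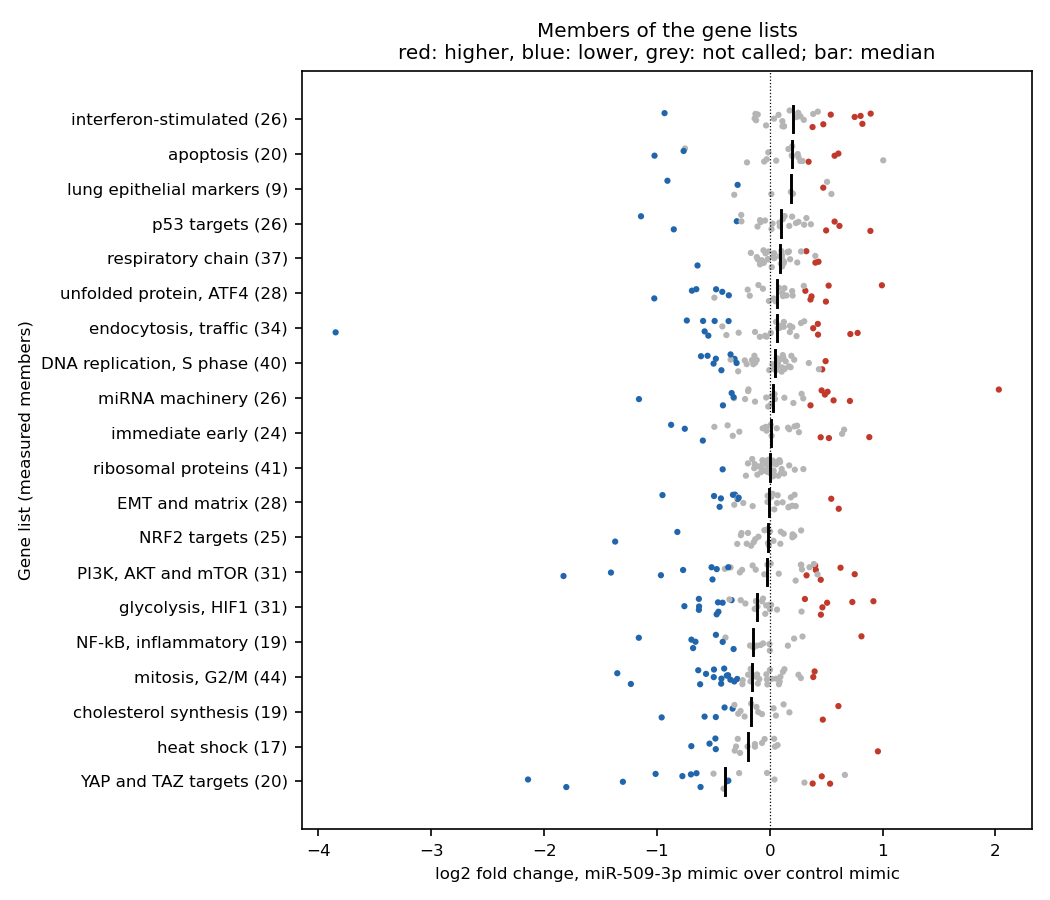
The log2 fold change of miR-509-3p mimic over control mimic (horizontal axis) of each measured member of the tested gene lists reported here (vertical axis, number measured in parentheses); points are genes, red where called higher, blue where called lower and grey otherwise, and black bars are list medians. The median was lowest for the YAP and TAZ targets, at -0.39,. It was 0.21 for interferon-stimulated genes, or 0.17 with 1 member undetected in 1 group at its bound.

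No other list passed the camera test, with limma camera adjusted p-values of 0.117 or more (Benjamini-Hochberg). In PI3K, AKT and mTOR signalling, 8 of 31 fell, 6 rose and 17 did not pass, with the same counts of calls adjusted over the list alone. PHLPP2, a phosphatase of AKT, fell by 1.83 ± 0.14, INPP4B, a phosphoinositide phosphatase, by 0.96 ± 0.12 and RPS6KB1, the S6 kinase, by 0.77 ± 0.08. In clathrin endocytosis and endosomal traffic, 7 of 34 fell, 5 rose and 22 did not pass, with 8 lower and 5 higher adjusted over the list alone. APPL1, an endosomal adaptor, fell by 0.74 ± 0.09, while the endocytic genes EPN1 and CLTB rose by 0.78 ± 0.08 and 0.71 ± 0.08. The median of this list, which includes RAB5C, was 0.06 and its mean -0.11, and the test pointed down. Without RAB5C, a choice made after the data were seen, the mean was 0.0013 and the test pointed up (limma camera adjusted p = 0.978, Benjamini-Hochberg). PIK3C2A is counted among the falls of the PI3K list.

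Of 40 measured genes of DNA replication and S phase, 8 fell, 2 rose and 30 did not pass, with 7 lower and 2 higher adjusted over the list alone. SLBP, the histone mRNA stem-loop binding protein, fell by 0.61 ± 0.09, E2F2 by 0.55 ± 0.08 and UHRF1 by 0.50 ± 0.08, and GINS4 rose by 0.49 ± 0.10. The median of this list was 0.05 and its mean -0.04, so they differed in sign, and the test pointed down. Of 26 measured p53 targets, 4 rose, 3 fell and 19 did not pass, with 4 higher and 2 lower adjusted over the list alone. TP53INP1 fell by 1.14 ± 0.11 and GDF15, a stress cytokine, by 0.85 ± 0.08, while SPATA18 rose by 0.89 ± 0.10 and XPC, a DNA damage sensor, by 0.62 ± 0.08. Of 20 apoptosis regulators, 3 rose, 2 fell and 15 did not pass, with the same counts of calls adjusted over the list alone. The pro-apoptotic genes BID and DIABLO fell by 1.02 ± 0.10 and 0.76 ± 0.07, and BCL2L2, an anti-apoptotic gene, and the death receptor gene TNFRSF10B rose by 0.61 ± 0.07 and 0.57 ± 0.10.

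Interferon-stimulated genes, which respond to double-stranded RNA, rose in 7 of 26 cases and fell in 1, and 18 did not pass, with 6 higher and 1 lower adjusted over the list alone. SAMD9 rose by 0.89 ± 0.14, the RNA sensor gene IFIH1 by 0.82 ± 0.10 and IFIT2 by 0.80 ± 0.08, and OAS3 fell by 0.93 ± 0.09. The camera test gave an adjusted p = 0.117, whereas fry, which tests only whether the genes of a list move one way on balance, gave 0.0374 (both limma, Benjamini-Hochberg). Of 19 NF-kB and inflammatory genes, 7 fell, 1 rose and 11 did not pass, with the same counts of calls adjusted over the list alone. IL32 fell by 1.16 ± 0.11, RELB, a subunit of NF-kB, by 0.69 ± 0.13 and CCL20, a chemokine, by 0.68 ± 0.09. PTGS2, the inducible cyclooxygenase, rose by 0.81 ± 0.09. The IL32 probe averaged only log2 6.78 on the mimic arrays, so the size of its fall rests partly on a level near background. The camera adjusted p was 0.117 and that of fry 0.0253 (both limma, Benjamini-Hochberg).

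Of 26 genes of miRNA processing and silencing, 7 rose, 4 fell and 15 did not pass, with 9 higher and 4 lower adjusted over the list alone. Besides DCP2, the exonuclease gene XRN1 and the deadenylation gene PAN3 rose by 0.71 ± 0.10 and 0.57 ± 0.10, whereas DCP1A, an activator of decapping, fell by 1.16 ± 0.14. Of 17 heat shock genes, 4 fell, 1 rose and 12 did not pass, with 6 lower and 1 higher adjusted over the list alone. The chaperone genes HSPA6, DNAJB1 and HSPA1A fell by 0.70 ± 0.16, 0.53 ± 0.07 and 0.48 ± 0.09, and HSPA1L rose by 0.96 ± 0.09. Of 28 genes of the unfolded protein response and ATF4, 6 rose, 6 fell and 16 did not pass, with the same counts of calls adjusted over the list alone. The amino acid transporter gene SLC3A2 fell by 1.02 ± 0.07, MTHFD2 by 0.69 ± 0.08 and ASNS by 0.65 ± 0.08, while TRIB3 rose by 0.99 ± 0.11. The median of this list was 0.07 and its mean -0.0079, and the test pointed down. Of 24 immediate early genes, 3 rose, 3 fell and 18 did not pass, with the same counts of calls adjusted over the list alone. FOS rose by 0.88 ± 0.17, and MYC, JUN and FOSL1 fell by 0.87 ± 0.08, 0.75 ± 0.12 and 0.59 ± 0.09. The median and mean of this list were 0.01 and 0.02, and the test pointed down.

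Among metabolic lists, 5 of 19 genes of cholesterol synthesis fell, 2 rose and 12 did not pass, with 6 lower and 2 higher adjusted over the list alone. INSIG1, a regulator of sterol sensing, fell by 0.96 ± 0.10, and the enzyme genes DHCR7 and HMGCS1 fell by 0.58 ± 0.09 and 0.48 ± 0.11. SREBF2, whose product drives this pathway, was not well above background in the controls and was at least 1.03-fold higher with the mimic. Of 31 genes of glycolysis and HIF1, 9 fell, 6 rose and 16 did not pass, with the same counts of calls adjusted over the list alone. SLC2A3, a glucose transporter, and P4HA2 rose by 0.92 ± 0.08 and 0.73 ± 0.08, and the enzyme genes ALDOC and HK1 fell by 0.76 ± 0.11 and 0.63 ± 0.09. Of 25 NRF2 targets, 2 fell, 0 rose and 23 did not pass, with the same counts of calls adjusted over the list alone. These were HMOX1, the inducible heme oxygenase, which fell by 1.37 ± 0.08, and SRXN1, which fell by 0.82 ± 0.08. Of 37 genes of the respiratory chain, 3 rose, 1 fell and 33 did not pass, with 1 lower and 0 higher adjusted over the list alone. NDUFV2, a subunit of complex I, fell by 0.64 ± 0.07, and NDUFA8, ATP5PB and ATP5PF rose by 0.43 ± 0.09, 0.40 ± 0.07 and 0.32 ± 0.08. Of 41 ribosomal protein genes, RPS23 fell by 0.42 ± 0.08 and the other 40 did not pass, and 0 passed adjusted over the list alone. Their median was 0.0051 and their mean -0.0065, and the test pointed down.

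Of 28 genes of epithelial and mesenchymal state and matrix, 8 fell, 2 rose and 18 did not pass, with the same counts of calls adjusted over the list alone. TWIST1, a transcription factor of mesenchymal state, fell by 0.95 ± 0.11 and COL4A2 by 0.49 ± 0.08, and ITGA5 and THBS1 rose by 0.61 ± 0.09 and 0.54 ± 0.14. For this list and for the NRF2 targets, the fry adjusted p was 0.0374 and the camera adjusted p 0.463 (both limma, Benjamini-Hochberg). Of 9 lung epithelial markers, 2 fell, 1 rose and 6 did not pass, with 3 lower and 2 higher adjusted over the list alone. The keratin gene KRT7 fell by 0.91 ± 0.09, the cadherin gene CDH1 by 0.29 ± 0.07, and MUC1 rose by 0.47 ± 0.10. Few markers of other cell types were measured. Of 12 fibroblast markers 3 were measured, of which THY1 rose by 0.95 ± 0.11. The endothelial marker ESAM, 1 of 10 listed, fell by 1.11 ± 0.09. Of 16 leukocyte markers 3 were measured, of which CD68 and CD14 rose by 0.93 ± 0.08 and 0.45 ± 0.10. The calls of these 3 marker lists were the same adjusted over the list alone. The second probes of MUC1, CD68 and CD14, at 0.17 ± 0.08, 0.39 ± 0.11 and 0.35 ± 0.19, did not pass. A further kept probe also did not pass for ASNS, ATP5PF, DIABLO, HSPA6 and IL32, each with the sign of the probe used.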

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

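Probes without a single gene name lie outside the gene comparison, and some of them differed from the control arrays. Of 3133 such probes, 328 were higher and 332 were lower with the miR-509-3p mimic (limma, Benjamini-Hochberg over probes), or 21.1%, and the others did not pass. Of the genes tested, 34.4% were called. Each gene was represented by its brightest kept probe and adjusted over genes, so the shares are not directly comparable. The genes of the unnamed probes were not analysed here, and no explanation was tested.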

How the results depend on the processing

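The 2-fold counts were added after the data had been seen. The 3 study targets kept their direction and their call under every alternative run. CDK2 lay between -2.39 and -1.67, PIK3C2A between -1.46 and -1.24 and RAC1 between -0.96 and -0.86. None of the 109 named genes changed direction under any alternative that tested it, but 48 lost their call without mimic 1 and 41 without mimic 2. With no filter on dim probes, 768 genes were called higher and 961 lower among 20039 genes tested. The adjusted p of CDK2 rose from 0.00226 to 0.0105 (limma, Benjamini-Hochberg), more than the added tests alone can give. The variance model was also refitted with the dim probes in it. Without each array in turn, the counts ranged from 270 to 1137 higher and from 556 to 1080 lower, with fewer arrays and a lone array assumed to vary like the other group. Without background correction, 459 genes were over 1.5-fold higher and 699 lower, and 62 and 213 over 2-fold. With the authors' processed values these were 463, 699, 62 and 212; background subtraction widens folds by its construction. The number of gene lists called went from 2 to 0 with an estimated correlation, 1 with no filter, 0 with probes averaged, and between 0 and 2 without each array. An estimated correlation alters only the p-value of a list (limma camera adjusted p = 0.574 for both, Benjamini-Hochberg), so the mean shifts of -0.20 for mitotic genes and -0.43 for YAP and TAZ targets are unchanged by construction. The mean shift of mitotic genes was -0.19 with probes averaged and ranged from -0.20 to -0.19 without each array. For YAP and TAZ targets it was -0.32 with no filter, -0.41 with probes averaged and -0.45 to -0.41 without each array. Without RAB5C, left out after the data had been seen, the mean of the endocytosis list turned from -0.11 to 0.0013, with no call in either. Apart from the fewer arrays, and the few degrees of freedom behind an estimated correlation, the cause was not tested for the lists. Median scaling, the stricter filter, the other variance model and an adjusted p under 0.1 left these counts within 1.5 times. The balance of calls, 1839 higher and 1685 lower, turned to 1312 higher and 1662 lower with median scaling and to 1306 and 1328 with the replicate block. It also turned with no filter and without each mimic array, at 270 and 556 without mimic 1 and 351 and 615 without mimic 2. Deviations of same-numbered arrays correlated at -0.05 across genes, so no shift common to many genes was seen. Whether same-numbered arrays shared a culture or slide cannot be told from this value. The seed match alternatives were not run. Signal over background limits 251 called genes, which were undetected on the arrays of 1 group.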

Other observations

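The gene lists in this part were formed after the data had been seen, and the tests of normalization and signal level on the surplus of falls were chosen only after that result was seen.

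Of 45 measured genes of motile cilia, 23 rose with the mimic, 2 fell and 20 did not pass, with a median log2 fold change of 0.64, or 0.47 with the 6 genes undetected in 1 group at their bound. The median was 0.33 without background correction, 0.32 with the authors' processed values and 0.15 with no filter on dim probes. Without the members seen first, 16 of 38 rose and 2 fell (limma camera unadjusted p = 0.00249, and unadjusted p = 0.0714 with an estimated correlation). PIERCE1, a microtubule inner protein of cilia, rose by 1.75 ± 0.09 (estimate ± SE), ODAD4, a docking protein of dynein arms, by 1.48 ± 0.18 and CFAP206 by 1.44 ± 0.09, while RSPH3, a radial spoke protein, fell by 1.59 ± 0.08. The intraflagellar transport genes, which build cilia, rose in 9 of 18 cases and fell in 0. Their median was 0.48, or 0.44 with the 2 genes undetected in 1 group at their bound. The median of these genes was 0.27 without background correction and 0.28 with the authors' processed values. Among them IFT27 rose by 1.74 ± 0.14 and IFT70B by 0.94 ± 0.10, and IFT22, undetected in the controls, was at least 1.95-fold higher. Without IFT27, which was seen first, 8 of 17 intraflagellar transport genes rose and 0 fell. Their median was 0.47, or 0.42 with the undetected genes at their bound. Over 70 families of gene names, the intraflagellar transport family and the zinc finger genes were the 2 called. The limma camera adjusted p was 0.00292 for each (Benjamini-Hochberg), and adjusted p = 0.995 with an estimated correlation. The limma fry adjusted p was 0.0579 for each (Benjamini-Hochberg), so neither passed that test. The estimated correlation was 0.078 for the intraflagellar transport family and 0.012 for the zinc finger genes, above the preset 0.01. Camera with an estimated correlation had little power on 2 residual degrees of freedom, so it cannot decide for these families or the cilia genes. Of 269 zinc finger genes, 86 rose, 14 fell and 169 did not pass. ZNF467 rose by 1.49 ± 0.10, ZNF805, undetected in the controls, was at least 2.42-fold higher, and ZNF362 fell by 1.39 ± 0.08. These examples were chosen after their values were seen.

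The rise of cilia genes was set against technical explanations. Without the members seen first, the median of the other 38 cilia genes was 0.32, above 99.98% of 10000 random lists matched on mean signal, whose highest was 0.34, which argues against signal level. This median was 0.12 with no filter on dim probes, where no matched lists were drawn. Median scaling, the 1 alternative that changed the step between arrays, gave 0.29, which argues against quantile normalization as the source. The lowest median with it, without background correction or with the authors' processed values was 0.26. An effect of miR-509-3p on cilia genes may be at work, as a hypothesis found and tested on the same arrays, and a slide effect or an action of the control mimic stays open.

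The zinc finger family had a median of 0.26, above all of 10000 matched lists, whose highest was 0.17, which argues against signal level. Median scaling gave 0.22, and the lowest median over the same 3 alternatives was 0.17, which argues against normalization. An effect of the mimic may account for the rise, as a hypothesis, with the slide and the control mimic open as above.

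More genes fell than rose by over 2-fold, 419 against 180, while the balance of all called genes depended on the treatment of the arrays, with 1839 higher and 1685 lower as first fitted and 1312 higher and 1662 lower with median scaling (limma, Benjamini-Hochberg). The 2-fold counts were 213 against 62 without background correction and 212 against 62 with the authors' processed values. The ratio of falls to rises over 2-fold was 2.78 with median scaling, the lowest of the same 3 alternatives, which argues against quantile normalization. Among genes above the median signal it was 2.54 (132 against 52), which argues against signal level. Direct silencing may contribute to the wide falls, but seed matches were not analysed here. An action of the control mimic cannot be told apart from it, since there were 0 arrays of untransfected cells.

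Probes of 10 of 2638 genes with several kept probes were called in both directions, while 562 genes had 2 or more called probes all in 1 direction. The probes of BTBD7, chosen after its values were seen, changed by 0.74 and -1.64. Probes for the precursors of MIR509-2 and MIR509-3 were undetected on all 4 arrays, and they do not measure the mature mimic. The probe for 18S ribosomal RNA, RNA18SN5, varied within groups, at log2 14.1 and 10.8 on the control arrays and 9.30 and 11.6 on the mimic arrays (limma adjusted p = 0.312, Benjamini-Hochberg).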
